A study of Homo sapiens and Mus musculus with 49 samples.

How the data were processed

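RNA was measured in 16 libraries of 5 sorted populations, 3 from blood and 2 from tonsil. Per the labels' protocols, RNA was extracted with the RNeasy Plus Micro kit, copied with the SMARTer low-input method and made into Nextera libraries. The deposited values are raw read counts per gene, as a table with 1 column per library. Per the submitters' processing notes, STAR, Picard and MACS2 and the genome build hg19 were used, with no versions and no roles for single data types, and no step that turned reads into counts is described. The strand setting and the annotation of the counting are not stated, nor are the sort gates. The gene identifiers include genes of alternate loci and of later annotations. The counts therefore carry no stated rule for reads that match several genes, overlapping genes or both strands. The other 33 samples of the series, chromatin libraries of human and mouse NK cells and 2 samples that no label placed in a group, were not analysed here, as the count table holds none of them.

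The table had 59297 lines, of which 288 repeated 1 of 247 genes with identical counts. Repeats were dropped, which left 59009 genes. XIST, TSIX and Y-linked genes (427 in all) were left out of everything that followed, and 58582 genes were kept. Symbols came from the table itself. A RefSeq gene table of assembly GRCh38.p14 was used to find Y-linked genes, to mark the MHC and KIR regions and for genomic spans matched by symbol, with no coordinates printed. It held 21421 of the genes. There were 1062 symbols with several identifiers in the count table, and none of them was named among the results, apart from the examples of few reads.

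Column names were matched to samples by population and donor number, and 0 columns were left without a sample. The 5 groups came from the labels. Donor numbers are given in the labels as donors, so equal numbers within blood, or within tonsil, pair the libraries. The check of that pairing used deviations from the group means over 7931 genes with a mean log2 CPM of at least 3. Of 11 same-donor pairs, 10 correlated above 0.1 (median r 0.56). The 31 pairs of different donors of the same tissue had a median r of -0.17, and 8 of them lay above 0.1. Subtracting the means of small groups itself pushes that median under 0. The 6 pairs of replicate 3 with replicate 8, which share no donor number, had a median r of 0.52. The check therefore does not tell a shared donor from a shared batch. In a check for exchanged libraries, 15 of 16 libraries correlated best with their own group.

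Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust fit, TMM scaling, filterByExpr by group) in R 4.3.3. All 16 libraries shared 1 estimate of the spread, and Benjamini-Hochberg adjustment ran over the 18828 genes tested per comparison. A gene was called at an adjusted p under 0.05. There were 6 comparisons, with no donor term. A fit with the donor as a block was run for the 4 comparisons within a tissue, on the libraries of that tissue alone. Log2 fold changes came from the same fit with the default prior count of edgeR, and log2 CPM values used a prior count of 1. An SE is the absolute log2 fold change over the square root of F. Levels are CPM from TMM-scaled totals, as means and SDs over libraries. Where a group held a few reads only, sums of reads are given in place of a fitted fold change. A limit of 3 counts was used for a library, or a group, with 0 reads. Limits from counts cover counting error only.

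In all, 34 gene lists were tested in 6 comparisons, 204 tests adjusted together. The lists held populations, functions and markers of other cell types. They were written with knowledge of published NK and innate lymphoid cell biology, so the directions of several were known beforehand and are descriptions of these populations. The test was two-sided camera of limma 3.58.1 with a preset correlation of 0.01, repeated with a correlation estimated per list. Of the 204 tests, 93 passed, all with a mean and a median fold change of the test's sign. With an estimated correlation 41 also passed, and a called list below passed there unless a failing value is printed. The genes called between both ends of the blood series were tested with camera in the tonsil comparison.

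Genes were named by a rule with 3 parts. The first was a panel of 16 genes. The second was, per comparison and direction, the 5 largest fold changes among called genes with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries, leaving out immunoglobulin and T cell receptor segments, polymorphic HLA genes, KIR and GSTM genes, and clone or small RNA symbols. The third was up to 4 members of smallest adjusted p from each list described. The rule admitted 787 pairs of a gene and a comparison, of which the text names 227. That subset was picked after the values and the outcomes of the alternatives had been seen.

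The comparisons, lists, naming rule and most alternatives were fixed before the data were examined. These alternatives were median-ratio and upper-quartile scaling, no filter on low counts, a filter of at least 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom with the donor as a random effect (correlation 0.331), only the compared groups, a fold change minimum, the donor block and leaving out each library in turn. After seeing the data were added a term for replicates 3 and 8, fits outside those replicates, the mean level of the myeloid and dendritic lists as a covariate, the term for replicates 3 and 8 for named genes, and upper-quartile scaling and no filter for gene lists. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the figures.

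The scripts were tested on simulated negative binomial counts with gene means, gene dispersions and totals estimated from these libraries, with 8-fold, 4-fold and 2-fold changes. For CD56dimCD57neg minus CD56bright, over 18087 genes, 50.7%, 18.8% and 0% of the changed genes were called, with 1 false call. For ieILC1 minus ILC3, over 18057 genes, the shares were 47.8%, 18.5% and 3%, with 2 false calls. In that comparison camera called 20 of 20 lists of 25 genes changed 2-fold and 0 of 60 unchanged lists, over 18034 genes. Genes were drawn independently there, so that test does not cover lists whose genes vary together.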

Results

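RNA from 5 sorted populations of human innate lymphocytes was sequenced as 16 libraries. Natural killer (NK) cells of blood were sorted as CD56bright cells (4 libraries), CD56dim cells without CD57 (CD56dimCD57neg, 3 libraries) and CD56dim cells with CD57 (CD56dimCD57pos, 3 libraries). CD56 is the adhesion molecule encoded by NCAM1, and CD57 is a carbohydrate made by the enzyme encoded by B3GAT1. From tonsil came intraepithelial group 1 innate lymphoid cells (ieILC1, 3 libraries) and group 3 innate lymphoid cells (ILC3, 3 libraries). Replicate numbers stand for donors, so that populations of blood came partly from the same donors, and both of tonsil from the same 3 donors. The main tests held no donor term and took the libraries as unpaired.

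Between 16000708 and 32369730 counts per library were assigned to genes, in 4 CD56bright libraries and 3 of each other group. A count of 0 in a single library allowed a level of up to 0.0927 to 0.187 CPM (counts scaled by library total), a limit that covers counting error only. Between 16832 and 18689 genes per library had at least 5 counts, and 18828 genes were tested. Levels below are means ± SD in CPM over the libraries of a group, the group named first in a comparison coming first, and log2 fold changes are given ± SE.

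**Figure D1:**
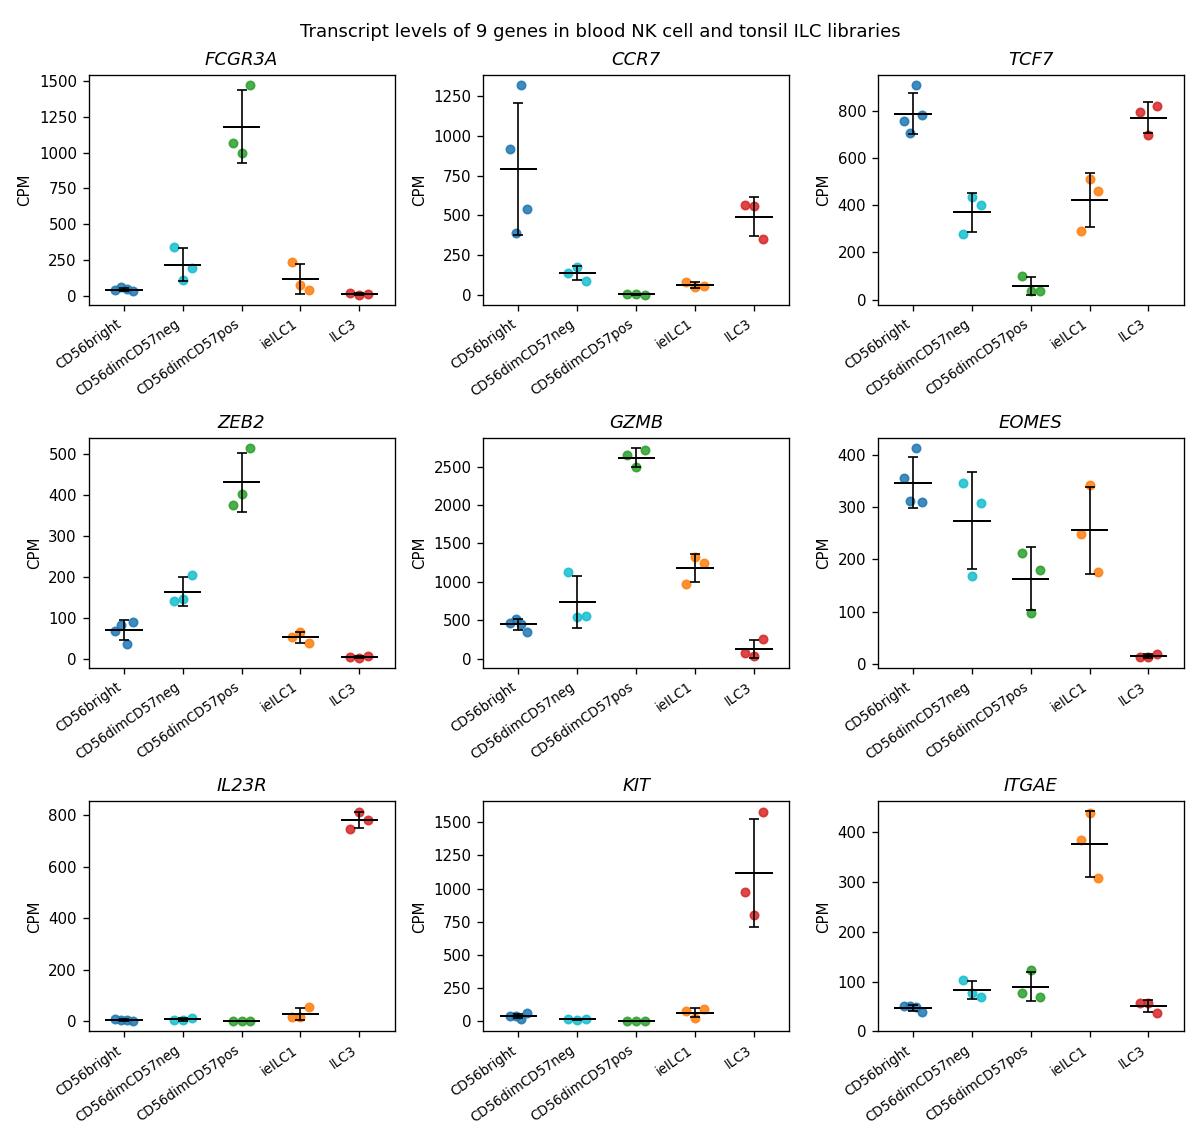
Each panel plots the level of 1 gene (vertical axis, CPM, linear) in the 5 populations (horizontal axis). Points are libraries, and horizontal and vertical bars are the mean and SD, with 4 libraries for CD56bright and 3 for each other group. The means of FCGR3A and ZEB2 were highest in CD56dimCD57pos, that of CCR7 in CD56bright, and those of IL23R and KIT in ILC3.

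The first comparison, CD56dimCD57neg (n = 3) against CD56bright (n = 4), addressed the loss of high CD56 in blood NK cells. Transcripts for surface and secreted products of CD56dim cells were higher, in libraries that also held many myeloid and dendritic transcripts. Which cells in these libraries made them was not tested. CX3CR1, a chemokine receptor of effector lymphocytes, was at 34.5 ± 14.9 against 1.54 ± 1.04 CPM, log2 fold change 4.48 ± 0.59 (edgeR adjusted p = 0.00187). The low-affinity IgG receptor gene FCGR3A, which encodes CD16, was at 217 ± 116 against 43.4 ± 11.2 CPM, log2 fold change 2.32 ± 0.51 (edgeR adjusted p = 0.0279). The chemokine receptor gene CXCR2 rose by 4.01 ± 0.77 on the log2 scale, the matrix protein gene SPON2 by 2.15 ± 0.39 and the steroid enzyme gene AKR1C3 by 2.64 ± 0.51. CCR7, a receptor for homing to lymph nodes, was lower at 135 ± 44.6 against 793 ± 417 CPM, log2 fold change -2.55 ± 0.48 (edgeR adjusted p = 0.0117), as was the transcription factor gene GATA3 at 94.1 ± 18.6 against 241 ± 52.2 CPM.

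The list of CD56dim surface and effector genes had 5 of 22 measured members called higher and 0 lower (11 and 0 adjusted over the list alone) and was higher (camera adjusted p = 9.96e-17). The list of CD56bright surface genes had 0 of 25 measured members called higher and 1 lower (0 and 8 adjusted over the list alone) and was lower (camera adjusted p = 2.72e-11). The list around TCF1, LEF1 and MYC had 0 of 20 measured members called higher and 1 lower (0 and 1 adjusted over the list alone), with the list as a whole lower (camera adjusted p = 1.09e-07). Its members TCF7, at 370.3 ± 82.8 against 788 ± 85.5 CPM, and IL7R, at 178 ± 68.5 against 682 ± 215 CPM, did not pass singly (edgeR adjusted p = 0.249 and 0.236). The list around PRDM1, ZEB2 and MAF had 1 of 16 measured members called higher and 0 lower (6 and 1 adjusted over the list alone) and was higher (camera adjusted p = 0.000575, adjusted p = 0.0698 with an estimated correlation). ZEB2 was at 165 ± 35.3 against 70.2 ± 24.4 CPM, NCAM1 at 143 ± 44.7 against 365 ± 74.7 CPM and KIT at 12.9 ± 4.08 against 39.4 ± 17.8 CPM, with edgeR adjusted p of 0.103, 0.0812 and 0.176. With the donor as a block, edgeR called ZEB2 (adjusted p = 0.02) and NCAM1 (adjusted p = 0.0095), and with a term for replicates 3 and 8 the adjusted p values were 0.0431 and 0.0261. Receptor genes higher in CD56dimCD57neg included CD160 (2.77 ± 0.50), SIGLEC9 (2.63 ± 0.57) and the integrin gene ITGA6 (2.35 ± 0.43). Among genes lower by the most were CDHR1 (-2.30 ± 0.53), MFGE8 (-2.17 ± 0.48), CABLES1 (-2.14 ± 0.51) and SRGAP3 (-1.79 ± 0.31).

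Transcripts of myeloid and dendritic cells were far higher in the same CD56dimCD57neg libraries. The myeloid marker list had 12 of 19 measured members called higher and 0 lower (18 and 0 adjusted over the list alone) (camera adjusted p = 6.83e-35, 0.00482 with an estimated correlation). The dendritic cell list had 4 of 10 measured members called higher and 0 lower (7 and 0 adjusted over the list alone) (camera adjusted p = 4.59e-10, 0.0226 with an estimated correlation). The lysozyme gene LYZ lay at 1329 ± 1121 CPM in CD56dimCD57neg, 53.5 ± 47.0 CPM in CD56bright and 7.06 ± 4.35 CPM in CD56dimCD57pos. FCER1A, an IgE receptor gene of dendritic cells and basophils, was at 356 ± 281 against 5.76 ± 4.90 CPM, log2 fold change 5.94 ± 0.95, and CD1C, a lipid-presenting molecule, at 219.5 ± 185 against 1.97 ± 3.07 CPM, log2 fold change 6.78 ± 1.12 (edgeR adjusted p = 0.00508 and 0.00632). Others were CLEC7A (6.33 ± 0.89), CSF3R (6.64 ± 1.00), MNDA (5.29 ± 0.89), FCN1 (5.99 ± 1.02) and FLT3 (7.38 ± 1.17). The genes with the greatest increases that the naming rule admitted were of this kind or near 0 in CD56bright. CD1E had 1953 reads over the 3 CD56dimCD57neg libraries and 6 over the 4 CD56bright libraries, CD1D had 725 and 2 and LMO2 had 1711 and 8. F13A1, a coagulation factor gene of monocytes and platelets, was at 67.1 ± 44.7 against 0.213 ± 0.102 CPM.

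Among antigen presentation genes, CD74 and CIITA were higher as well. CD74, the invariant chain of HLA class II, was at 15040 ± 10400 against 3241 ± 722 CPM, log2 fold change 2.21 ± 0.45 (edgeR adjusted p = 0.0186). Its transactivator CIITA was at 61.5 ± 57.2 against 9.95 ± 2.61 CPM, log2 fold change 2.63 ± 0.51 (edgeR adjusted p = 0.0139). The HLA class II list had 2 of 5 measured members called higher and 0 lower (2 and 0 adjusted over the list alone) (camera adjusted p = 0.00422, adjusted p = 0.204 with an estimated correlation). Of these 5 members, 3 have several identifiers and few reads, and the called ones were CD74 and CIITA. T cell markers had 2 of 26 measured members called higher and 0 lower (7 and 1 adjusted over the list alone) (camera adjusted p = 0.00769, adjusted p = 0.311 with an estimated correlation). The called members were CD4 (4.75 ± 1.03) and TRAT1 (3.37 ± 0.62). CD4 is also made by monocytes and dendritic cells. B cell markers had 1 of 12 measured members called higher and 0 lower (3 and 0 adjusted over the list alone) (camera adjusted p = 8.3e-05, adjusted p = 0.0749 with an estimated correlation). The cytokine receptor genes TNFRSF1A (3.40 ± 0.51) and IFNGR1 (2.19 ± 0.41), which myeloid cells also express, were higher.

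**Figure D2:**
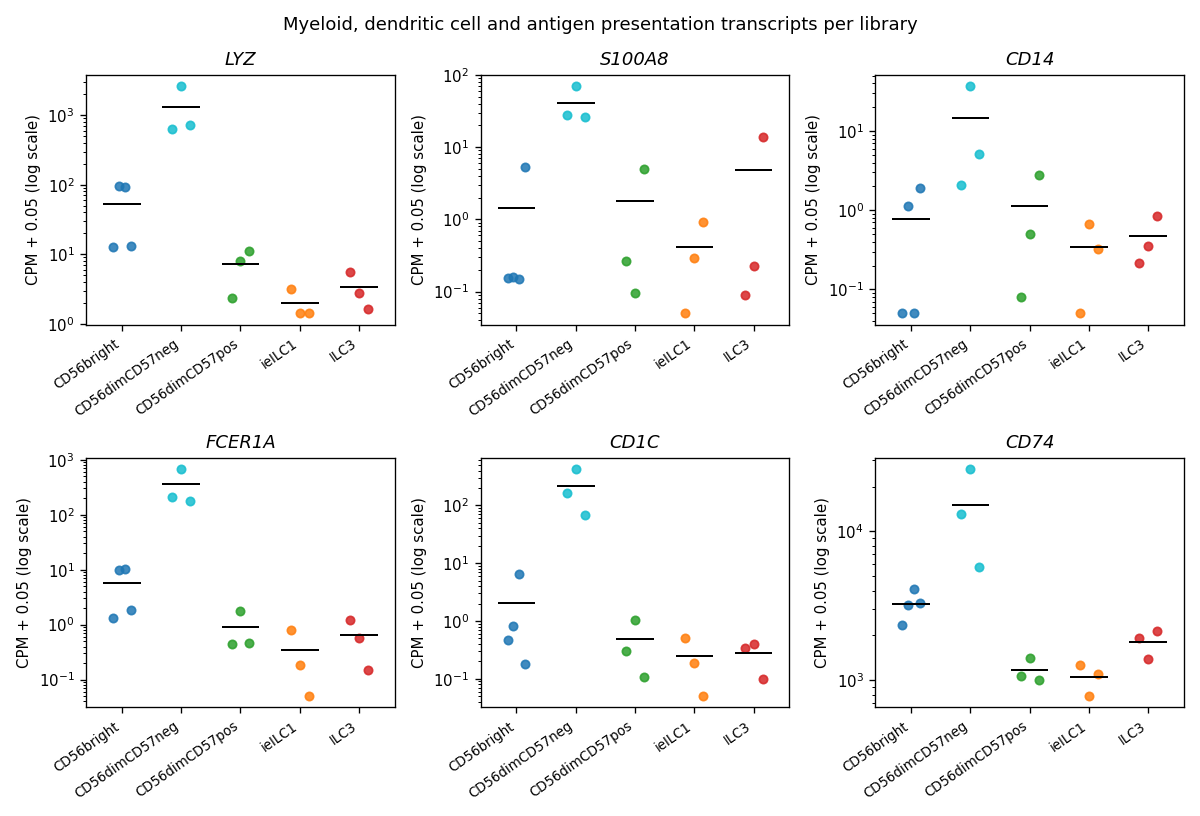
Each panel plots the level of 1 gene (vertical axis, CPM plus 0.05 on a log scale) in the 5 populations (horizontal axis), points being libraries and bars the mean over 4 CD56bright libraries or 3 libraries of each other group. In all 6 panels the mean was highest in CD56dimCD57neg.

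In all, edgeR called 253 genes, 237 higher and 16 lower in CD56dimCD57neg, and 582 and 114 with no filter on low counts. The count was 370 with a term for replicates 3 and 8 and 211 among the libraries outside them. With the mean level of the myeloid and dendritic markers as a covariate, edgeR called 0 genes, and 382 had an unadjusted p under 0.05; no other tool was run with the covariate. Of the variance of this covariate over the 7 libraries, 89.5% lay between the groups, whose values did not overlap, so that the lost calls do not tell the markers from the groups. Without CD56dimCD57neg replicate 7 the count was 56, and without CD56bright replicate 5, 6, 7 or 8 it was 88, 135, 166 or 121. It was 146 without CD56dimCD57neg replicate 5. Of the 31 named genes that passed, 19 lost their call without some library, and each of the 7 libraries ended at least 1 call. The highest edgeR adjusted p without 1 library was 0.176 for FCGR3A, 0.0648 for CXCR2, 0.0839 for AKR1C3, 0.0553 for CCR7, 0.134 for GATA3, 0.168 for SIGLEC9 and 0.065 for ITGA6. It was 0.196 for CDHR1, 0.21 for MFGE8, 0.214 for CABLES1, 0.0864 for LMO2, 0.0775 for MNDA, 0.0787 for FCN1, 0.0776 for FLT3, 0.212 for CD74, 0.271 for CIITA, 0.206 for CD4, 0.0533 for TRAT1 and 0.0578 for IFNGR1. The log2 fold change of CIITA fell to 1.51 without CD56dimCD57neg replicate 7. The block ended the calls of MFGE8 (edgeR adjusted p = 0.0678) and CIITA (0.0594). The HLA class II list lost its call without CD56dimCD57neg replicate 7 (camera adjusted p = 0.114) and the T cell list without CD56dimCD57neg replicate 8 (0.115) and outside replicates 3 and 8 (0.183). With that covariate, camera kept the calls of the CD56bright, CD56dim, TCF1, PRDM1 and T cell lists. It no longer called the HLA class II list (mean log2 fold change 0.59 without and -7.22 with the covariate, camera adjusted p = 0.15) or the B cell list (1.98 and 1.60, adjusted p = 0.346).

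The next comparison, CD56dimCD57pos against CD56dimCD57neg (n = 3 each), addressed the gain of CD57. B3GAT1, the enzyme that makes CD57, had 1560 reads over the 3 CD56dimCD57pos libraries and 3 over the 3 CD56dimCD57neg libraries. Several genes of cytotoxic cells were higher. The adhesion receptor gene ADGRG1 was at 287 ± 53.5 against 66.9 ± 13.7 CPM, log2 fold change 2.10 ± 0.47, the granzyme gene GZMH at 779 ± 145 against 152 ± 46.4 CPM, log2 fold change 2.36 ± 0.40 and FGFBP2 at 823 ± 209 against 69.9 ± 15.4 CPM, log2 fold change 3.56 ± 0.66 (edgeR adjusted p = 0.0193, 0.00262 and 0.00531). FCGR3A was at 1179 ± 253 against 217 ± 116 CPM, log2 fold change 2.44 ± 0.57 and the protease gene PRSS23 at 216 ± 103 against 19.5 ± 8.01 CPM, log2 fold change 3.47 ± 0.58 (edgeR adjusted p = 0.0241 and 0.00236). CCR7 was lower at 2.09 ± 1.11 against 135 ± 44.6 CPM (edgeR adjusted p = 6.76e-05).

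The list of CD57 and terminal maturation genes had 4 of 24 measured members called higher and 0 lower (8 and 1 adjusted over the list alone) (camera adjusted p = 5.8e-05, adjusted p = 0.0662 with an estimated correlation). The CD56dim list had 6 of 22 measured members called higher and 0 lower (16 and 0 adjusted over the list alone) (camera adjusted p = 6.68e-18). The CD56bright list had 0 of 25 measured members called higher and 12 lower (0 and 17 adjusted over the list alone) (camera adjusted p = 2.35e-27). Members of the latter that fell were IL7R (-3.17 ± 0.71), KIT (-2.73 ± 0.55), GPR183 (-5.90 ± 0.82), COTL1 (-5.60 ± 0.68), TNFRSF11A (-5.38 ± 0.68) and the granzyme gene GZMK (-5.20 ± 0.99). The TCF1, LEF1 and MYC list had 0 of 20 measured members called higher and 10 lower (0 and 14 adjusted over the list alone) (camera adjusted p = 4.91e-22). The transcription factor gene MYC was at 0.420 ± 0.0988 against 18.0 ± 6.90 CPM, log2 fold change -5.40 ± 0.62 and TCF7, which encodes TCF1, at 57.8 ± 36.4 against 370.3 ± 82.8 CPM, log2 fold change -2.68 ± 0.41 (edgeR adjusted p = 0.000234 and 0.00133). ZEB1 fell by 2.52 on the log2 scale (SE 0.44), while LEF1, at 3.29 ± 2.30 against 22.2 ± 10.9 CPM, did not pass (edgeR adjusted p = 0.0612, and 0.0196 with the donor block). The ILC3 marker list had 0 of 37 measured members called higher and 15 lower (1 and 25 adjusted over the list alone) (camera adjusted p = 7.43e-31). They included AHR (-2.93 ± 0.39). RUNX2 was at 7.17 ± 4.42 against 102 ± 42.8 CPM, log2 fold change -3.82 ± 0.51.

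The PRDM1, ZEB2 and MAF list had 0 of 16 measured members called higher and 0 lower (11 and 0 adjusted over the list alone) and was higher (camera adjusted p = 5.23e-07). ZEB2 was at 431 ± 72.8 against 165 ± 35.3 CPM (edgeR adjusted p = 0.0555) and MAF at 108 ± 30.3 against 40.1 ± 16.1 CPM (edgeR adjusted p = 0.111). The cytotoxic effector list had 2 of 24 measured members called higher and 1 lower (5 and 2 adjusted over the list alone) (camera adjusted p = 0.000204, adjusted p = 0.344 with an estimated correlation). The perforin gene PRF1 was at 1846 ± 1186 against 472 ± 176 CPM and the granzyme gene GZMB at 2619 ± 116 against 738 ± 338 CPM (edgeR adjusted p = 0.0808 and 0.0815). With the donor block edgeR called MAF (adjusted p = 0.0154), PRF1 (0.0103) and GZMB (0.0108). A term for replicates 3 and 8 gave adjusted p values of 0.019 for ZEB2, 0.0482 for LEF1, 0.0444 for PRF1 and 0.0499 for GZMB. Cell division genes were higher, with 2 of 32 measured members called higher and 0 lower (5 and 0 adjusted over the list alone) (camera adjusted p = 4.37e-07). They included BIRC5 (2.45 ± 0.55) and TK1 (2.85 ± 0.72). The genes that rose by the most under the naming rule were, besides those above, GOLM1 (3.61 ± 0.50), AK5 (3.84 ± 0.91), PCDH1 (4.57 ± 1.16) and CERCAM (4.88 ± 1.14).

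Myeloid and dendritic transcripts fell between the same libraries. The myeloid list had 0 of 19 measured members called higher and 13 lower (0 and 19 adjusted over the list alone) (camera adjusted p = 7.42e-29). The dendritic cell list had 0 of 10 measured members called higher and 7 lower (1 and 8 adjusted over the list alone) (camera adjusted p = 1.03e-11). LYZ was at 7.06 ± 4.35 against 1329 ± 1121 CPM, log2 fold change -7.56 ± 1.05, with FCER1A (-8.70 ± 1.23), CD1C (-8.96 ± 1.43), CLEC7A (-7.14 ± 1.06) and MNDA (-7.42 ± 1.12) (edgeR adjusted p = 0.000766 for LYZ). CD74 was at 1164 ± 224 against 15040 ± 10400 CPM, log2 fold change -3.69 ± 0.53 and CIITA at 1.53 ± 0.843 against 61.5 ± 57.2 CPM, log2 fold change -5.30 ± 0.65 (edgeR adjusted p = 0.000838 and 0.000388). The HLA class II list had 0 of 5 measured members called higher and 2 lower (0 and 3 adjusted over the list alone) (camera adjusted p = 8.2e-05, adjusted p = 0.0755 with an estimated correlation). B cell markers had 0 of 12 measured members called higher and 3 lower (1 and 7 adjusted over the list alone) (camera adjusted p = 1.68e-06). The genes that fell by the most under the naming rule were near 0 in CD56dimCD57pos. GPAT3 had 1 read there and 1750 in CD56dimCD57neg, EPB41L3 had 1 and 1099, ACPP had 1 and 984, WDFY4 had 3 and 2031 and CACNA2D3 had 2 and 1313, each over 3 libraries.

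In all, edgeR called 500 genes, 48 higher and 452 lower in CD56dimCD57pos. With DESeq2 188 were higher and 764 lower, and with limma-voom and the donor as a random effect 208 and 609. The count was 678 with a term for replicates 3 and 8 and 356 outside them, and 2 with the myeloid and dendritic marker level as a covariate (392 at an unadjusted p under 0.05). It was 269 without CD56dimCD57neg replicate 7, 235 without CD56dimCD57pos replicate 5 and 275 without CD56dimCD57pos replicate 6. Of the 36 named genes that passed, 13 lost their call without some library, and each of the 6 libraries ended at least 1 call. The highest edgeR adjusted p without 1 library was 0.125 for FCGR3A, 0.0857 for ADGRG1, 0.168 for PCDH1, 0.0988 for CERCAM, 0.127 for IL7R, 0.0545 for KIT, 0.0554 for GZMK, 0.106 for BIRC5 and 0.18 for TK1. It was 0.076 for EPB41L3, 0.0518 for WDFY4, 0.0888 for CACNA2D3 and 0.443 for AK5, whose log2 fold change was 1.98 without CD56dimCD57pos replicate 5. The block ended the calls of PCDH1 (edgeR adjusted p = 0.122) and CERCAM (0.117). Of the variance of the covariate, 92.3% lay between these groups, again with no overlap. With it, camera kept the calls of the CD56bright, CD56dim, TCF1, ILC3, cell division and B cell lists. It no longer called the CD57 list (mean log2 fold change 0.90 without and 0.19 with the covariate, camera adjusted p = 0.15) or the PRDM1, ZEB2 and MAF list (0.98 and 0.49, adjusted p = 0.213). Nor did camera call the cytotoxic list (0.48 and -0.02, adjusted p = 0.749) or the HLA class II list (-2.74 and 6.67, adjusted p = 0.634).

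The comparison of CD56dimCD57pos (n = 3) with CD56bright (n = 4) spanned both ends of the blood series. Several genes of effector function were higher. FCGR3A was at 1179 ± 253 against 43.4 ± 11.2 CPM, log2 fold change 4.76 ± 0.56, CX3CR1 at 129 ± 54.8 against 1.54 ± 1.04 CPM, log2 fold change 6.38 ± 0.63 and FGFBP2 at 823 ± 209 against 17.7 ± 11.7 CPM, log2 fold change 5.54 ± 0.64 (edgeR adjusted p = 8.51e-05, 2.56e-05 and 8.51e-05). GZMB was at 2619 ± 116 against 445 ± 69.3 CPM, log2 fold change 2.56 ± 0.49 (edgeR adjusted p = 0.00413). CCR7 was lower at 2.09 ± 1.11 against 793 ± 417 CPM, log2 fold change -8.55 ± 0.64, as was IL7R, which encodes a receptor chain for interleukin-7, at 19.8 ± 22.1 against 682 ± 215 CPM, log2 fold change -5.11 ± 0.76 (edgeR adjusted p = 3.3e-06 and 0.000672).

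The CD56dim list had 18 of 22 measured members called higher and 0 lower (19 and 0 adjusted over the list alone) (camera adjusted p = 5.91e-36). They included SPON2 (3.99 ± 0.41), CXCR2 (6.25 ± 0.83), GZMH (2.90 ± 0.37), PRSS23 (4.26 ± 0.53) and ADGRG1 (3.76 ± 0.45). The CD57 and terminal maturation list had 9 of 24 measured members called higher and 2 lower (11 and 3 adjusted over the list alone) (camera adjusted p = 6.3e-07). B3GAT1 was at 20.6 ± 6.00 against 0.254 ± 0.237 CPM. The CD56bright list had 0 of 25 measured members called higher and 17 lower (0 and 20 adjusted over the list alone) (camera adjusted p = 1.92e-37). They included KIT (-4.34 ± 0.58), GPR183 (-6.43 ± 0.83), TNFRSF11A (-7.08 ± 0.72), COTL1 (-5.30 ± 0.66) and SPINK2 (-8.13 ± 1.45). The cytotoxic effector list had 6 of 24 measured members called higher and 2 lower (11 and 2 adjusted over the list alone) (camera adjusted p = 0.000136, adjusted p = 0.327 with an estimated correlation). Among its members GZMK (-5.71 ± 1.00) and CRTAM (-3.28 ± 0.60), an adhesion receptor gene, were lower.

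Transcription factor genes divided along the series. The TCF1, LEF1 and MYC list had 0 of 20 measured members called higher and 15 lower (0 and 16 adjusted over the list alone) (camera adjusted p = 2.23e-28). TCF7 was at 57.8 ± 36.4 against 788 ± 85.5 CPM, log2 fold change -3.77 ± 0.42, LEF1 at 3.29 ± 2.30 against 64.0 ± 24.6 CPM, log2 fold change -4.27 ± 0.78 and MYC at 0.420 ± 0.0988 against 40.6 ± 26.6 CPM, log2 fold change -6.57 ± 0.64 (edgeR adjusted p = 6.79e-05, 0.00305 and 2.35e-05) and ZEB1 (-3.49 ± 0.45). The PRDM1, ZEB2 and MAF list had 10 of 16 measured members called higher and 1 lower (12 and 1 adjusted over the list alone) (camera adjusted p = 1.51e-11). ZEB2 was at 431 ± 72.8 against 70.2 ± 24.4 CPM, log2 fold change 2.62 ± 0.35, MAF at 108 ± 30.3 against 24.0 ± 7.13 CPM, log2 fold change 2.17 ± 0.40 and PRDM1 at 477 ± 167 against 74.2 ± 46.0 CPM, log2 fold change 2.68 ± 0.74 (edgeR adjusted p = 0.000228, 0.00367 and 0.0452). EOMES, at 164 ± 59.8 against 347 ± 48.2 CPM, TBX21, with log2 fold change 0.90 ± 0.35, and NCAM1, at 211 ± 59.7 against 365 ± 74.7 CPM, did not pass (edgeR adjusted p = 0.0874, 0.172 and 0.23). With the donor block, edgeR called EOMES lower (adjusted p = 0.0313) and TBX21 higher (0.024). The ILC3 marker list had 1 of 37 measured members called higher and 21 lower (1 and 24 adjusted over the list alone) (camera adjusted p = 3.77e-27). They included AFF3 (-7.77 ± 0.70) and AHR (-3.27 ± 0.38). The transcription factor gene RUNX2 (-4.56 ± 0.52), not in that list, was also lower.

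Cell division genes were higher, with 8 of 32 measured members called higher and 0 lower (14 and 0 adjusted over the list alone) (camera adjusted p = 2.35e-08). They included BIRC5 (4.22 ± 0.54), MKI67 (2.21 ± 0.41), STMN1 (2.51 ± 0.47) and TK1 (2.54 ± 0.64). T cell markers had 5 of 26 measured members called higher and 3 lower (8 and 6 adjusted over the list alone) (camera adjusted p = 0.707). They included CD6 (5.55 ± 0.84), CD3D (3.82 ± 0.65) and BCL11B (3.32 ± 0.49). Dendritic cell markers had 1 of 10 measured members called higher and 1 lower (1 and 4 adjusted over the list alone) (camera adjusted p = 0.023, adjusted p = 0.294 with an estimated correlation). LYZ was lower at 7.06 ± 4.35 against 53.5 ± 47.0 CPM, log2 fold change -2.93 ± 0.83 (edgeR adjusted p = 0.0499). By the naming rule, the greatest increases also held CMKLR1 (7.65 ± 1.17), a chemoattractant receptor gene. The greatest decreases held MSRB3 with 1 read over the CD56dimCD57pos libraries and 1266 over the CD56bright libraries, ZNF521 with 3 and 1098, and COL24A1 with 4 and 1088.

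In all, edgeR called 953 genes, 458 higher and 495 lower in CD56dimCD57pos. The count was 1542 with the donor as a block, 1456 with a term for replicates 3 and 8 and 652 outside those replicates. It was 522 with the myeloid and dendritic marker level as a covariate. Without CD56bright replicate 5 it was 629, without CD56dimCD57pos replicate 5 it was 466 and without CD56dimCD57pos replicate 6 it was 573. Of the 41 named genes that passed, 3 lost their call without some library, each of the 7 libraries ending at least 1 of these calls, with edgeR adjusted p up to 0.138 for PRDM1, 0.103 for TK1 and 0.224 for LYZ. The term for replicates 3 and 8 also ended the call of LYZ (edgeR adjusted p = 0.0681). The dendritic cell list lost its call without CD56bright replicate 7 (camera adjusted p = 0.0621), without CD56dimCD57pos replicate 5 (0.0612) or 8 (0.104), outside replicates 3 and 8 (0.105) and with a stricter filter on low counts (0.0605).

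In tonsil, ieILC1 were compared with ILC3 (n = 3 each), an NK-related against a helper population of the same donors. Which cells made the transcripts in tonsil libraries, which also held T cell transcripts, was not tested. The transcription factor genes EOMES and TBX21 were higher in ieILC1, at 256 ± 83.0 against 15.7 ± 3.54 CPM, log2 fold change 4.03 ± 0.41, and at 91.8 ± 28.4 against 6.23 ± 2.75 CPM, log2 fold change 3.88 ± 0.43 (edgeR adjusted p = 0.000165 and 0.000232). ITGAE, the integrin chain CD103 that binds epithelial cadherin, was at 376 ± 65.3 against 50.2 ± 11.9 CPM, log2 fold change 2.90 ± 0.32 (edgeR adjusted p = 0.000232). KIT was lower at 63.7 ± 33.7 against 1122 ± 410 CPM, log2 fold change -4.14 ± 0.57, as was the interleukin-23 receptor gene IL23R at 27.8 ± 22.3 against 783 ± 32.5 CPM, log2 fold change -4.82 ± 0.73 (edgeR adjusted p = 0.00101 and 0.00197).

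The ILC3 marker list had 0 of 37 measured members called higher and 20 lower (0 and 26 adjusted over the list alone) (camera adjusted p = 5.91e-36). They included IL1R1 (-4.73 ± 0.64), IL7R (-3.68 ± 0.72) and the protocadherin gene PCDH9 (-5.65 ± 0.69). The list of ieILC1 and tissue residence genes had 13 of 38 measured members called higher and 0 lower (18 and 0 adjusted over the list alone) (camera adjusted p = 4.97e-27). They included CD160 (5.03 ± 0.62) and ITGA1 (4.01 ± 1.01). The cytotoxic effector list had 8 of 24 measured members called higher and 0 lower (14 and 1 adjusted over the list alone) (camera adjusted p = 2.17e-17). They included GZMH (3.29 ± 0.42), GZMA (4.57 ± 0.68), GZMB (3.26 ± 0.56) and PRF1 (3.88 ± 0.61). NK receptor genes had 9 of 26 measured members called higher and 1 lower (11 and 2 adjusted over the list alone) (camera adjusted p = 3.06e-08, adjusted p = 0.14 with an estimated correlation). They included KLRF1 (3.44 ± 0.62), SLAMF7 (3.01 ± 0.59) and the adaptor gene SH2D1A (3.36 ± 0.51). FCGR3A was at 117 ± 103 against 13.1 ± 4.88 CPM, log2 fold change 3.16 ± 0.58 (edgeR adjusted p = 0.00749). The TGF-beta response list had 4 of 26 measured members called higher and 0 lower (7 and 3 adjusted over the list alone) (camera adjusted p = 0.000136). They included TGFBR3 (1.38 ± 0.29). Cytokines and chemokines had 3 of 29 measured members called higher and 6 lower (4 and 9 adjusted over the list alone) (camera adjusted p = 0.047, adjusted p = 0.579 with an estimated correlation). The growth factor gene CSF2 was at 31.7 ± 25.8 against 437 ± 174 CPM, log2 fold change -3.79 ± 0.69 (edgeR adjusted p = 0.0068).

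The factors of the blood series did not all follow 1 direction in tonsil. The PRDM1, ZEB2 and MAF list had 5 of 16 measured members called higher and 1 lower (6 and 1 adjusted over the list alone) (camera adjusted p = 2.23e-05). ZEB2 was higher in ieILC1, at 53.0 ± 14.3 against 5.46 ± 2.15 CPM, log2 fold change 3.28 ± 0.40, and MAF lower, at 29.0 ± 2.45 against 221 ± 126 CPM, log2 fold change -2.93 ± 0.46 (edgeR adjusted p = 0.000425 and 0.00257). PRDM1, at 67.5 ± 49.3 against 19.1 ± 13.8 CPM, did not pass (edgeR adjusted p = 0.329), but did with the donor block (0.00791) and with a term for replicates 3 and 8 (0.0442). The TCF1, LEF1 and MYC list had 1 of 20 measured members called higher and 3 lower (1 and 3 adjusted over the list alone) (camera adjusted p = 0.0033, adjusted p = 0.0566 with an estimated correlation). CCR7 was lower in ieILC1, at 61.9 ± 16.7 against 492 ± 121 CPM, while MYC was higher at 47.5 ± 8.40 against 8.80 ± 3.46 CPM, log2 fold change 2.43 ± 0.52 (edgeR adjusted p = 0.00385 and 0.017). TCF7 was at 421 ± 114 against 770.3 ± 65.9 CPM, LEF1 at 15.8 ± 3.10 against 14.4 ± 17.8 CPM and NCAM1 at 227 ± 57.3 against 228 ± 82.8 CPM, none of which passed (edgeR adjusted p = 0.338, 0.971 and 1). Cell division genes were higher in ieILC1, with 5 of 32 measured members called higher and 0 lower (10 and 0 adjusted over the list alone) (camera adjusted p = 1.01e-12). They included MKI67 (2.57 ± 0.46), BIRC5 (2.64 ± 0.55) and MCM2 (2.12 ± 0.45). Myeloid markers had 0 of 19 measured members called higher and 2 lower (0 and 2 adjusted over the list alone) (camera adjusted p = 0.0418, adjusted p = 0.553 with an estimated correlation).

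Under the naming rule, the greatest decreases in ieILC1 also held RBMS3 (-7.46 ± 0.99), COL24A1 (-6.50 ± 1.26) and SLCO2A1 (-6.18 ± 1.09), with the chemokine receptor genes CCR4 at 1 read over the ieILC1 libraries and 814 over the ILC3 libraries, and CCR8 at 9, with 2 of 3 ieILC1 libraries at 0, and 1589. The greatest increases were DRAXIN (5.29 ± 0.66), CDH17 (5.02 ± 1.02), STOX2 (5.00 ± 0.96) and GEM (4.58 ± 1.16), beside CD160.

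In all, edgeR called 466 genes, 245 higher and 221 lower in ieILC1. More genes were lower than higher with limma-voom and the donor as a random effect (645 higher and 890 lower), with no filter on low counts (407 and 532), with DESeq2 (497 and 530) and with the donor block (465 and 504). That was also so without ILC3 replicate 1 (99 and 105) or 2 (67 and 80) and with the 6 libraries alone (76 and 77). The count was 969 with the donor as a block in the tonsil libraries alone, 764 with a term for replicates 3 and 8 and 382 outside those replicates. It was 152 without ieILC1 replicate 2, 204 without ILC3 replicate 1 and 147 without ILC3 replicate 2. Fitting the 6 libraries alone gave 153, and with the myeloid and dendritic marker level as a covariate the count was 208. Of the 36 named genes that passed, 14 lost their call without ieILC1 replicate 1 or 2 or ILC3 replicate 1, 2 or 3. The highest edgeR adjusted p was 0.203 for ITGA1, 0.064 for SLAMF7, 0.058 for FCGR3A, 0.0859 for BIRC5, 0.108 for MCM2, 0.104 for MYC, 0.0843 for IL7R, 0.0533 for CSF2, 0.062 for SLCO2A1, 0.0907 for CDH17, 0.0659 for STOX2 and 0.117 for TGFBR3. It was 0.0591 for CCR8 and 0.239 for GEM. Their log2 fold changes were -12.02 without ieILC1 replicate 3, against a group then at 0, and 7.09 without ILC3 replicate 3. The cytokine list lost its call without ieILC1 replicate 1 (camera adjusted p = 0.347) or 2 (0.0706) or ILC3 replicate 3 (0.201), with the term for replicates 3 and 8 (0.106) and with no filter on low counts (0.232). The myeloid list lost its call without ieILC1 replicate 1 (camera adjusted p = 0.142) or 2 (0.0983) or ILC3 replicate 1 (0.118) or 3 (0.0597), with that term (0.0777) and with no filter (0.0938).

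The blood series was then set against the tonsil populations, which share no library with it. The 495 genes higher in CD56bright than in CD56dimCD57pos had a mean log2 fold change of -1.05 between ieILC1 and ILC3 (camera p = 6.66e-15, and p = 0.000164 with an estimated correlation). The 458 genes higher in CD56dimCD57pos had a mean of 0.942 (camera p = 8.92e-25, and p = 0.00104 with an estimated correlation). Of the former, 67 were called higher in ILC3 and 12 higher in ieILC1, where independent lists would share 5.81 and 6.44. Of the latter, 81 were called higher in ieILC1 and 11 higher in ILC3, where independent lists would share 5.96 and 5.38. Across 18828 genes, which are not independent replicates, Spearman's rho of both fold changes was 0.318.

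**Figure D3:**
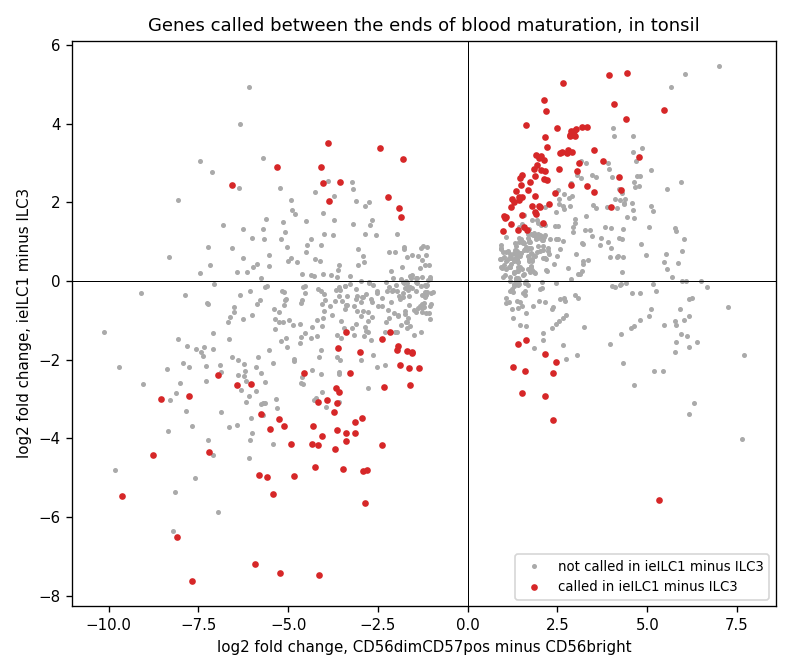
Each point is a gene called between CD56dimCD57pos and CD56bright, with that log2 fold change on the horizontal axis and the log2 fold change of ieILC1 minus ILC3 on the vertical axis, red where edgeR also called it in tonsil. Of the 458 genes to the right of 0, 81 were called higher in ieILC1 and 11 higher in ILC3.

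The comparison of ieILC1 (n = 3) with CD56bright (n = 4) set a tonsil population against its blood counterpart with high CD56. Tissue, donors and population all differed and cannot be told apart, and again the source cells were not tested. Integrin genes of tissue residence were higher in ieILC1, with ITGAE at 376 ± 65.3 against 47.5 ± 5.93 CPM, log2 fold change 2.99 ± 0.29 and ITGA1, which encodes CD49a, at 488 ± 282 against 2.01 ± 1.31 CPM, log2 fold change 7.91 ± 1.06 (edgeR adjusted p = 1.84e-05 and 0.000266). The activating receptor gene NCR2, which encodes NKp44, was at 246 ± 102 against 2.26 ± 0.686 CPM, log2 fold change 6.76 ± 0.41 (edgeR adjusted p = 1.31e-07). The sphingosine phosphate receptor gene S1PR1, which acts in recirculation, was lower at 4.25 ± 0.720 against 231 ± 79.0 CPM, log2 fold change -5.77 ± 0.51 (edgeR adjusted p = 8.81e-06).

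The ieILC1 and tissue residence list had 10 of 38 measured members called higher and 1 lower (15 and 1 adjusted over the list alone) (camera adjusted p = 2.94e-08). They included ENTPD1 (3.40 ± 0.40), TGFBR1 (2.35 ± 0.31) and TGFBR3 (-2.35 ± 0.29). The TGF-beta response list, which also holds these genes and both integrin genes, had 9 of 26 measured members called higher and 2 lower (11 and 3 adjusted over the list alone) (camera adjusted p = 4.17e-05). NK receptor genes had 6 of 26 measured members called higher and 2 lower (8 and 2 adjusted over the list alone) (camera adjusted p = 0.00221, adjusted p = 0.461 with an estimated correlation). They included CD160 (3.56 ± 0.52). Also lower were CCR7 (-3.68 ± 0.51), ITGAM (-3.61 ± 0.43) and KLF2 (-3.06 ± 0.56), a transcription factor gene of lymphocyte trafficking. The TCF1, LEF1 and MYC list had 1 of 20 measured members called higher and 7 lower (3 and 11 adjusted over the list alone) (camera adjusted p = 0.00187, adjusted p = 0.0506 with an estimated correlation). TBX21, at 91.8 ± 28.4 against 90.4 ± 20.4 CPM, and EOMES, at 256 ± 83.0 against 347 ± 48.2 CPM, did not pass (edgeR adjusted p = 0.981 and 0.429). Cell division genes were higher, with 17 of 32 measured members called higher and 0 lower (23 and 0 adjusted over the list alone) (camera adjusted p = 1.81e-12). They included BIRC5 (4.55 ± 0.54), MCM2 (2.75 ± 0.42), MCM4 (2.60 ± 0.42) and MKI67 (2.33 ± 0.42).

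Cytokines and chemokines had 10 of 29 measured members called higher and 2 lower (11 and 2 adjusted over the list alone) (camera adjusted p = 0.00216, adjusted p = 0.408 with an estimated correlation). They included FASLG (4.07 ± 0.62) and IL32 (2.63 ± 0.41). Of 24 measured cytotoxic genes, 3 were called higher and 2 lower (6 and 4 adjusted over the list alone). The list did not pass (camera adjusted p = 0.669), and GNLY (-1.91 ± 0.51) and FGFBP2 (-3.52 ± 0.66) were lower. T cell markers were higher in the same libraries, with 7 of 26 measured members called higher and 0 lower (9 and 1 adjusted over the list alone) (camera adjusted p = 3.13e-05, adjusted p = 0.119 with an estimated correlation). The T cell receptor alpha constant gene TRAC was at 464 ± 356 against 25.8 ± 9.91 CPM, log2 fold change 4.17 ± 0.57 and CD3D at 41.4 ± 22.6 against 1.10 ± 0.636 CPM, log2 fold change 5.23 ± 0.68 (edgeR adjusted p = 0.000299 and 0.00023), with TRAT1 (7.44 ± 0.71) and ICOS (6.26 ± 0.83). Under the naming rule, the greatest increases also held WIPF3 (8.05 ± 0.98), CDH17 with 1651 reads over the ieILC1 libraries and 3 over the CD56bright libraries, STOX2 with 1089 and 3, and FCRL4 with 1063 and 4. The greatest decreases held EFHC2 (-8.18 ± 0.59), RAP1GAP2 (-7.07 ± 0.66), ZNF521 with 2 and 1098 reads, TSPAN18 with 4 and 1265 and KLF3-AS1 with 3 and 1060. KLF3-AS1 is an antisense gene, and since the strand setting of the counting was not stated its reads cannot be told apart from those of its partner.

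In all, edgeR called 2269 genes, 1321 higher and 948 lower in ieILC1, and 1002 and 1192 with upper-quartile scaling, which moved the median log2 fold change of all genes from 0.026 to -0.153. The count was 3535 with a term for replicates 3 and 8 and 1440 outside those replicates, 980 with the myeloid and dendritic marker level as a covariate and 1218 without ieILC1 replicate 2. Of the 32 named genes that passed, GNLY lost its call without ieILC1 replicate 1 or 3 (edgeR adjusted p up to 0.073). The cytokine list lost its call without ieILC1 replicate 3 (camera adjusted p = 0.112).

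ILC3 (n = 3) were likewise compared with CD56bright (n = 4), a blood population that also expresses KIT and IL7R. Tissue, donors, population and source cells again cannot be told apart. IL23R was at 783 ± 32.5 against 4.40 ± 2.55 CPM, log2 fold change 7.47 ± 0.73 and the interleukin-1 receptor gene IL1R1 at 410.4 ± 168 against 5.14 ± 3.38 CPM, log2 fold change 6.31 ± 0.61 (edgeR adjusted p = 1.16e-05 and 1.16e-05). KIT was at 1122 ± 410 against 39.4 ± 17.8 CPM, log2 fold change 4.83 ± 0.53 and IL7R at 5654 ± 658 against 682 ± 215 CPM, log2 fold change 3.05 ± 0.63 (edgeR adjusted p = 2.72e-05 and 0.00472). The NK cell factors EOMES, at 15.7 ± 3.54 against 347 ± 48.2 CPM, log2 fold change -4.47 ± 0.41, and TBX21, at 6.23 ± 2.75 against 90.4 ± 20.4 CPM, log2 fold change -3.86 ± 0.42, were lower (edgeR adjusted p = 1.03e-05 and 2.72e-05).

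The ILC3 marker list had 26 of 37 measured members called higher and 1 lower (28 and 1 adjusted over the list alone) (camera adjusted p = 2.88e-26). They included NCR2 (7.39 ± 0.43) and the survival factor gene TNFSF13B (5.92 ± 0.79). Cytokine receptors had 15 of 33 measured members called higher and 7 lower (17 and 8 adjusted over the list alone) (camera adjusted p = 0.00203). Cytokines and chemokines had 12 of 29 measured members called higher and 2 lower (16 and 2 adjusted over the list alone) (camera adjusted p = 4.74e-06, adjusted p = 0.215 with an estimated correlation). IL22, an epithelial barrier cytokine, was at 225 ± 86.0 against 0.506 ± 0.286 CPM, log2 fold change 8.75 ± 1.22 (edgeR adjusted p = 0.000233), and TNFSF10, which encodes TRAIL, at 337 ± 65.2 against 61.5 ± 24.6 CPM. The chemokine gene CCL20 had 4077 reads over the ILC3 libraries and 2 over the CD56bright libraries, and IL2 had 1106 and 1. CCL1 had 949 reads over the ILC3 libraries (15.4 ± 23.8 CPM) and 0 over the CD56bright libraries, so that its level was at least 345-fold higher against a limit of 3 counts over the group, and at least 41.1-fold without ILC3 replicate 3.

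The CD56dim list had 0 of 22 measured members called higher and 12 lower (0 and 16 adjusted over the list alone) (camera adjusted p = 1.98e-13). FCGR3A was at 13.1 ± 4.88 against 43.4 ± 11.2 CPM, log2 fold change -1.73 ± 0.53 (edgeR adjusted p = 0.043). The cytotoxic effector list had 1 of 24 measured members called higher and 14 lower (3 and 14 adjusted over the list alone) (camera adjusted p = 1.09e-08, adjusted p = 0.119 with an estimated correlation). They included GZMH (-4.23 ± 0.43), GZMA (-3.69 ± 0.64) and KLRF1 (-3.55 ± 0.61). The PRDM1, ZEB2 and MAF list had 1 of 16 measured members called higher and 9 lower (1 and 10 adjusted over the list alone) (camera adjusted p = 1.21e-07). ZEB2 was lower at 5.46 ± 2.15 against 70.2 ± 24.4 CPM and MAF higher at 221 ± 126 against 24.0 ± 7.13 CPM (edgeR adjusted p = 2.41e-05 and 0.000134). TCF7 was at 770.3 ± 65.9 against 788 ± 85.5 CPM and did not pass (edgeR adjusted p = 0.965), while MYC (-2.21 ± 0.50) and S1PR1 (-3.12 ± 0.45) were lower. T cell markers were higher in the same libraries, with 7 of 26 measured members called higher and 0 lower (7 and 2 adjusted over the list alone) (camera adjusted p = 0.00136, adjusted p = 0.252 with an estimated correlation). They included TRAC (4.96 ± 0.59), TRAT1 (5.92 ± 0.67) and ICOS (9.10 ± 0.91), a costimulatory receptor gene that ILC3 also express. Under the naming rule, the greatest increases also held B3GALT5 with 2065 reads over the ILC3 libraries and 1 over the CD56bright libraries, and SORCS1 with 1426 and 1. The greatest decreases held ZMAT4 (-7.76 ± 1.29), RAP1GAP2 with 9 and 2187 reads, SGSM1 with 8 and 1157, ZNF521 with 10 and 1098 and NNMT with 7 and 756.

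In all, edgeR called 2210 genes, 1345 higher and 865 lower in ILC3, and 1109 and 1159 with upper-quartile scaling, which moved the median of all genes from 0.022 to -0.144. The count was 3529 with a term for replicates 3 and 8 and 1596 outside those replicates, 1283 without ILC3 replicate 1 and 1221 without ILC3 replicate 2. Of the 31 named genes that passed, FCGR3A lost its call without CD56bright replicate 5, 6 or 7 or ILC3 replicate 1, 2 or 3 (edgeR adjusted p up to 0.171). The T cell list lost its call without ILC3 replicate 3 (camera adjusted p = 0.0536).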

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

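The tests below of myeloid cells in the sort, of the share of NK cells, of uncounted reads, of a library batch and of sequencing depth were chosen only after the results were seen, while those of silent genes, of gene length and of other splits of the libraries were not.

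Levels of 109 named genes and 5 library measures were searched for a CD56bright library (the one group of 4) far from the other 3. The search found 14 of 114 (12.3%). Any reads against 0 in the others pass, so no chance rate holds. Replicate 7 stood apart for the myeloid genes MNDA, at 7.98 CPM against 0.783 to 1.34 CPM in the other 3 libraries, and CD1C, at 6.56 CPM against 0.131 to 0.764 CPM. It also stood apart for BIRC5, at 1.91 CPM against 0.914 to 1.08 CPM. Replicate 6 had CIITA at 6.05 CPM against 10.8 to 11.6 CPM, CMKLR1 at 0.873 CPM against 0 to 0.0516 CPM, PRSS23 at 20.7 CPM against 7.15 to 8.94 CPM and BCL11B at 11.9 CPM against 5.19 to 6.09 CPM. Replicate 5 had MCM4 at 4.95 CPM against 8.03 to 8.16 CPM. In replicate 8, 17336 genes had at least 5 counts, against 16852 to 16902 in the other 3. The remaining values lay at or under the limit of a few reads, with CD1D at 0.0979 CPM and SORCS1 at 0.049 CPM in replicate 7, IL2 at 0.0516 CPM in replicate 5, B3GALT5 at 0.0545 CPM in replicate 6, each against 0 CPM, and STOX2 at 0 CPM in replicate 8 against 0.049 to 0.0545 CPM.

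Myeloid and dendritic transcripts were high in all 3 CD56dimCD57neg libraries, LYZ at 1329 ± 1121 CPM. A lower share of NK cells would raise the markers of all other types alike only if NK cells made none. Among markers under 10 CPM in CD56bright, the median log2 fold change was 4.93 for 25 myeloid and dendritic genes. It was 1.58 for 28 markers of T cells, B cells, red cells and platelets. The difference of 3.35 does not decide this, as both sets rose. Its SE of 0.58, from resampling genes that vary together, does not cover the spread between libraries. Myeloid or dendritic cells within the sorted fraction may be a source, since 92% of the 25 markers (23) were highest in the same library, replicate 7, as a varying share of such cells would give. No sort gate is stated in the labels. Expression by NK cells themselves was not tested.

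Genes with several identifiers in the table, such as those with copies on alternate loci, had few reads. Among genes outside the MHC and KIR regions, 89.8% of 472 with several identifiers lay under 1 CPM, against 40.1% of 17839 with 1 identifier, a ratio of 2.24, which is consistent with reads that match several copies of a gene not having been counted. That these genes are silent in these cells is argued against by ribosomal protein genes, which every cell uses: 3 with several identifiers had a median of 1.22 CPM and 80 with 1 identifier had 302 CPM, a ratio of 0.00404. Over all libraries the means were 0.0285 CPM for TAP1, 0.0112 CPM for TNF, 0.00452 CPM for LTB, 0.113 CPM for CCL3 and 0.0704 CPM for CCL4. No such gene was named in a comparison, but some entered list tests, among them 3 of 5 tested members of the HLA class II list, 3 of the CD57 list and all 3 tested KIR genes.

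The libraries of replicates 3 (tonsil) and 8 (blood) deviated together from their group means. All 6 correlations between the tissues lay between 0.38 and 0.71, against a range of -0.60 to 0.58 for 54 other pairs across tissues (median -0.03, 17 over 0.1), which overlaps with them, and a library batch shared by replicates 3 and 8 is a candidate explanation that the labels do not record. Gene length remains open, with a Spearman rho of -0.26 between the mean deviation and the genomic span over 94.5% of 7931 genes, between the bounds set beforehand. Sequencing depth also remains open, as these replicates had the lowest totals in 4 of 5 groups. No biological explanation was tested for this pattern.

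Other splits of the same libraries were refitted for each comparison. For ieILC1 minus CD56bright, 1 of 35 splits, the real one, gave as many calls (2269, at most 15 in the other splits). The same held for ILC3 minus CD56bright (2210 and 182). Every other split mixes both populations within a group, which widens the spread and leaves few calls. Replicates 3 and 8 also deviated together, so these libraries cannot be freely exchanged. Chance is therefore not excluded by these counts. For CD56dimCD57neg minus CD56bright (253 and 6) and CD56dimCD57pos minus CD56bright (953 and 62) it was also 1 of 35, but these splits ignore the donors. The real splits part 3 donor pairs, as do 8 splits of the 35, and of these the highest other gave 6 and 0 calls, while those parting fewer pairs gave at most 0 and 62. These 8 splits are too few for a share under 0.05. For CD56dimCD57pos minus CD56dimCD57neg (500, and at most 0 in the others) and ieILC1 minus ILC3 (466 and 90), the 10 splits are too few for a share under 0.05.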

How the results depend on the processing

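The term for replicates 3 and 8, the fits outside these replicates, the covariate, and upper-quartile scaling and no filter for gene lists were chosen only after the results were seen. For CD56dimCD57neg minus CD56bright, CD56dimCD57pos minus CD56dimCD57neg, CD56dimCD57pos minus CD56bright and ieILC1 minus ILC3, edgeR called 253, 500, 953 and 466 genes, in this order. With no filter on low counts the counts were 696, 1048, 1627 and 939, and with limma-voom and the donor as a random effect 572, 817, 2066 and 1535. DESeq2 called 529, 952, 1797 and 1027, and 3664 for ieILC1 minus CD56bright (2269 with edgeR) and 3403 for ILC3 minus CD56bright (2210). Fits with the donors as a replicate block used the libraries of 1 tissue alone. CD56dimCD57pos minus CD56bright then gave 1542 calls and ieILC1 minus ILC3 gave 969, and no other count changed by over 1.5 times. With a term for replicates 3 and 8 these gave 1456 and 764, ieILC1 minus CD56bright gave 3535 and ILC3 minus CD56bright 3529. Outside these replicates ieILC1 minus CD56bright gave 1440, and only the compared groups gave 153 for ieILC1 minus ILC3. With the myeloid and dendritic marker level as a covariate, edgeR called 0 (382 at an unadjusted p under 0.05), 2 (392), 522 and 208, and 980 for ieILC1 minus CD56bright. Of the variance of this covariate, 89.5%, 92.3%, 87.6% and 71.9% lay between the groups of the first 2 comparisons, of ieILC1 minus ILC3 and of ieILC1 minus CD56bright, with no overlap, so there it nearly restates the groups. For these counts the cause was not tested, except that a leave-out or a fit of fewer groups has fewer libraries. With counts given above, the split of higher and lower calls moved by over 10 percentage points for CD56dimCD57neg minus CD56bright with no filter. It also did for CD56dimCD57pos minus CD56dimCD57neg with DESeq2 and limma-voom, and for ieILC1 minus ILC3 with limma-voom. So it did for ieILC1 and ILC3 minus CD56bright with upper-quartile scaling. By less than that, the majority also turned for ieILC1 minus ILC3 with no filter, DESeq2, the block, the compared groups alone and without ILC3 replicate 1 or 2. It turned for CD56dimCD57pos minus CD56bright from 458 and 495 to 1101 and 965 with limma-voom and 370 and 331 without CD56dimCD57pos replicate 8, and for ieILC1 minus CD56bright to 1822 and 1842 with DESeq2.

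Leaving out each library in turn gave 56 to 289 calls for CD56dimCD57neg minus CD56bright, 235 to 465 for CD56dimCD57pos minus CD56dimCD57neg, 466 to 732 for CD56dimCD57pos minus CD56bright, 147 to 455 for ieILC1 minus ILC3, 1218 to 2084 for ieILC1 minus CD56bright and 1221 to 1826 for ILC3 minus CD56bright. A log2 fold change of at least 1 was met by 2211 and 2140 of the calls in the last 2 comparisons. No paired analysis was possible for ieILC1 or ILC3 minus CD56bright, as blood and tonsil share no donor numbers.

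Of 204 list tests, 93 passed, and 41 with a correlation estimated per list. The count was 93 with median-ratio scaling, 92 with upper-quartile scaling, 101 with no filter, 83 of 180 with the stricter filter, 94 with the term for replicates 3 and 8, 93 outside them (82 of the 93 kept) and 83 with the covariate (68 kept). With the block, 65 of 126 passed against 60, 59 of them the same. No called list was called in the other direction in any of these fits. Where run, the mean tonsil fold change lay between -1.417 and -0.888 for genes higher in CD56bright. For those higher in CD56dimCD57pos it lay between 0.753 and 1.205, each past the threshold. No run used upper-quartile scaling, other count filters, a fold change minimum, DESeq2, limma-voom or only the compared groups.

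Of the named genes, 4 values near 0 that did not pass changed sign, and the cause was not tested. In ieILC1 minus ILC3, LEF1 (0.13) ranged from -0.32 to 1.95 over the leave-outs. NCAM1 (under 0.01 in size) ranged from -0.27 to 0.22 over them, and was 0.06 with the block and 0.05 with the term for replicates 3 and 8. In ieILC1 minus CD56bright, TBX21 (0.02) was -0.02 with median-ratio scaling and with DESeq2, and ranged from -0.15 to 0.26 over the leave-outs. In ILC3 minus CD56bright, TCF7 (-0.03) ranged from -0.09 to 0.04. DESeq2 called every named gene that edgeR called. Named calls held in every leave-out for 12 of 31, 23 of 36, 38 of 41, 22 of 36, 31 of 32 and 30 of 31 genes, in the order above. Depth limits what genes under about 0.187 CPM can show in a single library.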

Other observations

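The term for replicates 3 and 8, the fits outside them and the covariate were chosen only after the results were seen. The lists described here were fixed with the others.

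Between CD56dimCD57neg (n = 3) and CD56bright (n = 4), the glycolysis list had 4 of 22 measured members called higher and 0 lower (7 and 0 adjusted over the list alone) (camera adjusted p = 1.85e-06, adjusted p = 0.0848 with an estimated correlation). The homing and adhesion list had 5 of 36 measured members called higher and 1 lower (10 and 2 adjusted over the list alone) (camera adjusted p = 0.00351, adjusted p = 0.0799 with an estimated correlation and 0.131 with the donor block). With the covariate, 89.5% of whose variance lay between these groups, the mean log2 fold change went from 0.80 to 0.28 for glycolysis (camera adjusted p = 0.664) and from 0.75 to 1.10 for homing and adhesion (camera adjusted p = 0.115). These values do not tell the markers from the groups. Plasma cell markers had 1 of 6 measured members called higher and 0 lower (4 and 0 adjusted over the list alone) (camera adjusted p = 0.000305). The ribosomal protein list had 0 of 81 measured members called higher and 0 lower (0 and 0 adjusted over the list alone) (camera adjusted p = 0.055, 0.87 with an estimated correlation, 0.000556 with the donor block and 0.934 without CD56dimCD57neg replicate 5).

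Between CD56dimCD57pos and CD56dimCD57neg (n = 3 each), markers of mast cells and basophils had 0 of 4 measured members called higher and 2 lower (0 and 2 adjusted over the list alone) (camera adjusted p = 9.34e-06).

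Between ieILC1 and ILC3 (n = 3 each), genes of ribosome biogenesis had 0 of 63 measured members called higher and 0 lower (0 and 0 adjusted over the list alone) (camera adjusted p = 0.000612, adjusted p = 0.294 with an estimated correlation), the list as a whole being higher in ieILC1. Immediate early and stress genes had 2 of 39 measured members called higher and 0 lower (2 and 0 adjusted over the list alone) (camera adjusted p = 2.97e-05, adjusted p = 0.405 with an estimated correlation). That call was lost with the covariate, 87.6% of whose variance lay between these groups (mean log2 fold change 0.70 without and 0.28 with it, camera adjusted p = 0.0694). The list of NK cell and innate lymphoid transcription factors had 9 of 72 measured members called higher and 6 lower (14 and 8 adjusted over the list alone) (camera adjusted p = 0.00685, adjusted p = 0.28 with an estimated correlation). Interferon-stimulated genes had 0 of 38 measured members called higher and 0 lower (0 and 0 adjusted over the list alone) (camera adjusted p = 0.849). Markers of group 2 innate lymphoid cells had 0 of 6 measured members called higher and 0 lower (0 and 0 adjusted over the list alone) (camera adjusted p = 0.0845, 0.462 with an estimated correlation, 0.0232 with the donor block, 0.393 outside replicates 3 and 8 and up to 0.358 with 1 library left out).

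Between ieILC1 (n = 3) and CD56bright (n = 4), 6 further lists were lower in ieILC1. CD56dim surface genes had 1 of 22 measured members called higher and 4 lower (4 and 6 adjusted over the list alone) (camera adjusted p = 0.0304, adjusted p = 0.36 with an estimated correlation), a call lost without ieILC1 replicate 1 (camera adjusted p = 0.141). Immediate early and stress genes had 1 of 39 measured members called higher and 4 lower (1 and 6 adjusted over the list alone) (camera adjusted p = 0.0418, adjusted p = 0.749 with an estimated correlation). That call was lost without CD56bright replicate 5 (camera adjusted p = 0.274) or 8 (0.27) or ieILC1 replicate 1 (0.234) and outside replicates 3 and 8 (0.0803). Myeloid markers had 0 of 19 measured members called higher and 3 lower (0 and 4 adjusted over the list alone) (camera adjusted p = 0.00703, adjusted p = 0.407 with an estimated correlation). Dendritic cell markers had 0 of 10 measured members called higher and 3 lower (1 and 7 adjusted over the list alone) (camera adjusted p = 0.0345, adjusted p = 0.36 with an estimated correlation), a call lost without CD56bright replicate 7 (camera adjusted p = 0.0705), without ieILC1 replicate 3 (0.112) and outside replicates 3 and 8 (0.0776). Ribosomal protein genes had 0 of 81 measured members called higher and 2 lower (0 and 0 adjusted over the list alone) (camera adjusted p = 2.15e-05, adjusted p = 0.69 with an estimated correlation). Genes encoded by mitochondria had 0 of 13 measured members called higher and 0 lower (0 and 0 adjusted over the list alone) (camera adjusted p = 0.0383, adjusted p = 0.643 with an estimated correlation), a call lost without CD56bright replicate 5 (camera adjusted p = 0.224) or 8 (0.0513) or ieILC1 replicate 1 (0.204).

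Between ILC3 (n = 3) and CD56bright (n = 4), immediate early and stress genes had 1 of 39 measured members called higher and 11 lower (1 and 18 adjusted over the list alone) (camera adjusted p = 1.61e-07, adjusted p = 0.312 with an estimated correlation). Genes encoded by mitochondria had 0 of 13 measured members called higher and 4 lower (0 and 7 adjusted over the list alone) (camera adjusted p = 6.44e-05, adjusted p = 0.33 with an estimated correlation). Ribosomal protein genes had 0 of 81 measured members called higher and 4 lower (0 and 0 adjusted over the list alone) (camera adjusted p = 1.46e-09, adjusted p = 0.535 with an estimated correlation). Nuclear genes of oxidative phosphorylation had 1 of 47 measured members called higher and 1 lower (1 and 1 adjusted over the list alone) (camera adjusted p = 0.0484, adjusted p = 0.81 with an estimated correlation). That call was lost without CD56bright replicate 5 (camera adjusted p = 0.0666) or 8 (0.191) or ILC3 replicate 1 (0.401) or 2 (0.144), with the stricter filter (0.0577) and with the covariate (0.102). Epithelial markers, of which 4 were measured, had 2 of 4 measured members called higher and 0 lower (3 and 0 adjusted over the list alone) (camera adjusted p = 0.00884, adjusted p = 0.0566 with an estimated correlation). That call was lost without ILC3 replicate 1 (camera adjusted p = 0.0704) or 3 (0.0951) and outside replicates 3 and 8 (0.123). Stromal and endothelial markers had 1 of 7 measured members called higher and 0 lower (1 and 0 adjusted over the list alone) (camera adjusted p = 0.08). Red cell and platelet markers had 0 of 6 measured members called higher and 0 lower (0 and 0 adjusted over the list alone) (camera adjusted p = 0.471). For KIR genes, most of which have several identifiers, camera gave an adjusted p of 0.415.

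Library measures were compared without a test. The share of counts in mitochondrial genes was 5.57 ± 2.21% (SD, n = 4) in CD56bright, 5.37 ± 1.07% in CD56dimCD57neg, 6.50 ± 1.93% in CD56dimCD57pos, 4.24 ± 1.14% in ieILC1 and 3.41 ± 1.09% in ILC3 (n = 3 each). The 50 genes with the most counts held 26.0 ± 2.41%, 25.5 ± 3.06%, 24.5 ± 0.392%, 18.9 ± 1.95% and 18.9 ± 1.24% of the counts in the same order.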
